A study of Mus musculus with 24 samples.

How the data were processed

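The study used 24 Affymetrix mouse arrays, 1 for the gastrocnemius (a calf muscle) and 1 for the heart of each of 12 male mice aged 2 months. The 12 animals formed 4 groups of 3 per tissue. Wild type and Cmah knockout mice carry the strain label C57BL/6J, whereas mdx and Cmah knockout mdx mice carry C57BL6/10J. RNA input was 25 ng per array, amplified with a NuGEN Ovation kit. Per the submitters' processing notes the authors used GCOS and RMA, and no version of either is given. The deposited values are linear intensity values for 45101 probe sets, with array medians between 41.9 and 50.7.

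The 64 control probe sets were set aside and the log2 of the other 45037 was taken. Gene symbols came from the platform annotation, which gives 1 symbol for 34945 probe sets, several for 932 and none for 9160. Of those with 1 symbol, 34741 matched a gene in a table of the GRCm38.p6 assembly by gene number, and that assembly was used for names and for which genes neighbour each other, besides the planned window of 20 Mb to either side of Cmah. The array annotation names no assembly, so no positions are given.

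Within each tissue a probe set was tested when at least 3 of the 12 arrays lay above the 40th percentile of all values of that tissue. A model with the mean of each of the 4 groups was fitted with limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided moderated tests), and the Benjamini-Hochberg adjusted p had to lie below 0.05. Dystrophin loss was read as mdx against wild type and as Cmah knockout mdx against Cmah knockout. Cmah loss was read as Cmah knockout against wild type and as Cmah knockout mdx against mdx, and an interaction term compared both readings of Cmah loss. Differences between the tissues were fitted over all 24 arrays with animal as a random block, using limma's duplicateCorrelation (consensus correlation 0.217, reused in the repeats that left out an array). Errors of log2 changes are standard errors from limma, and errors of group means are SD.

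These comparisons, the alternatives first listed below and 38 gene lists (muscle fibre types, cell types, matrix, immune, metabolic and stress programmes and sialic acid biology) were chosen before the data were examined. Of 668 list entries, 666 matched a current symbol in the GRCm38.p6 gene table, which does not say how many the array measures. Lists were tested with camera in limma on 1 probe set per gene, the one with the highest mean over the 12 arrays of the tissue. The correlation between genes was preset to 0.01 and p was adjusted over the 38 lists of a comparison. Each test was repeated with an estimated correlation and with fry, whose directional test asks whether a list's genes move, on balance, one way without comparing them with other genes. Tissue differences of lists were tested with the preset form of camera on the moderated statistics of the difference.

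Genes were named by a fixed rule. Dmd, Cmah and Nnt were always named. For each comparison the rule took up to 10 genes with the largest rise and up to 10 with the largest fall among those past the threshold without overlap between the groups, and, where fewer than 5 passed in a direction, those with the smallest p up to 5, given as values. For a list it took up to 4 members with the largest change among those that passed, or up to 2 with the smallest p as values. Named genes were read from the probe set with 1 symbol and the highest mean. Uqcr10, Ctsl and Msr1, which passed at other probe sets, were chosen after their values were seen. Not every gene that the rule allows is printed, above all in heart, where none passed.

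Array quality was read from the log2 difference of the 3' and 5' Gapdh control probe sets, from the upper quartile of intensities and from correlations between arrays. No pair of arrays was identical. After the data were seen, 3 sets of 4 animals, 1 of each genotype, were found from the deviations of the gastrocnemius arrays from their group means, and were used as a block and for values within sets. Of 216 ways to form such sets this one had the highest mean correlation of deviations within sets in gastrocnemius (0.460, next 0.411). In heart it ranked 5 (0.271), and 1 without the 2 deviating arrays (0.653, next 0.638), so that the sets are less certain there. Set 1 stood apart in the Gapdh difference and in the bioB control in gastrocnemius (log2 11.29 to 11.69, against 9.36 to 10.60 in the other 8 arrays), so the sets may follow array quality as well as the animals, which was not tested. A block found from the arrays themselves lowers the residual spread, so its counts can be too high. In gastrocnemius it also makes the differences within sets more alike, which favours equal signs across the sets. Equal signs and list calls kept with the block are therefore no independent support. No label gives a batch or a date. The alternatives covered the filter, the scaling, the variance model, the arrays in the fit, the replicate numbers or the animal as a block, and leaving out each array in turn. Chosen after the data were seen were the block of animal sets, array weights, leaving out animal set 1, leaving out the 2 deviating hearts, both scalings for the lists, and leaving out each array in the list differences between the tissues.

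The procedure was tested on simulated data drawn gene by gene from the wild type means and residual spreads of the real arrays, with known changes added to the mdx arrays. Its genes are independent of each other, unlike those of real tissue. It was run once per tissue with few changed probe sets, so the shares recovered are rough. For changes of 1, 2 and 4 on the log2 scale, limma recovered 1.47%, 48.5% and 83.3% in gastrocnemius and 1.47%, 9.09% and 62.1% in heart. In these simulations 8.33% and 4.0% of the calls were unchanged probe sets. A list raised by 1 was called in both tissues by camera with the preset and with the estimated correlation.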

Results

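Gene expression was measured in the gastrocnemius and heart of 12 mice that differed in 2 genes. Dmd encodes dystrophin, the protein missing in mdx mice, a model of Duchenne muscular dystrophy. Cmah encodes the enzyme that makes N-glycolylneuraminic acid, a sialic acid that humans lack. Each tissue held 3 wild type, 3 Cmah knockout, 3 mdx and 3 Cmah knockout mdx animals, and the number of arrays limits the precision of every value. The comparisons ask what loss of each gene changes, and whether Cmah loss changes the dystrophic muscle. Both comparisons across dystrophin loss also cross the strain labels C57BL/6J and C57BL6/10J, and so does the interaction.

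Dmd itself was lower in dystrophin-deficient gastrocnemius. Its brightest probe set read 10.16 ± 0.10 log2 intensity in wild type, 10.15 ± 0.14 in Cmah knockout, 8.37 ± 0.28 in mdx and 8.18 ± 0.56 in Cmah knockout mdx (SD, n = 3). The fall by 1.96 ± 0.31 in Cmah knockout mdx against Cmah knockout passed limma's test (Benjamini-Hochberg adjusted p = 0.0388), and the difference of -1.80 ± 0.31 in mdx against wild type did not (adjusted p = 0.187, or 0.0387 with the animal sets as a block). The call was lost when any 1 of the 6 arrays except Cmah knockout mdx replicate 1 was left out, with limma adjusted p between 0.121 without Cmah knockout replicate 1 and 0.184 without Cmah knockout mdx replicate 3 (0.139, 0.177 and 0.149 without Cmah knockout replicates 2 and 3 and Cmah knockout mdx replicate 2), with log2 changes of Dmd between -2.09 and -1.64. It was also lost in a fit of these groups alone (adjusted p = 0.134), with both tissues in the fit (0.0686), with the replicate numbers as a block (0.0527) and without animal set 1 (0.110). In heart the same probe set read 9.96 ± 0.10 in wild type, 9.25 ± 1.10 in Cmah knockout, 8.86 ± 0.37 in mdx and 8.52 ± 0.33 in Cmah knockout mdx, with no comparison past the threshold. With array weights, Dmd in heart passed in mdx against wild type (-0.92, adjusted p = 0.0386). Without the 2 heart arrays that deviate in quality, the difference of Dmd in heart between Cmah knockout mdx and Cmah knockout was -1.39 in place of -0.73. The brightest Cmah probe set passed the threshold in no comparison. Whether its probes lie in the deleted part of the gene is not known, so its values do not speak for or against the knockout labels. In gastrocnemius it read 7.38 ± 0.46 in wild type, 6.36 ± 0.56 in Cmah knockout, 7.21 ± 0.84 in mdx and 7.16 ± 0.85 in Cmah knockout mdx, with no overlap between wild type and Cmah knockout (-1.03 ± 0.52). In heart it read 6.66 ± 1.54, 6.50 ± 1.20, 6.78 ± 0.33 and 6.95 ± 1.12 in the same order. Nnt, a mitochondrial gene that is partly deleted in C57BL/6J, differed by -0.15 ± 0.34 in gastrocnemius and 0.10 ± 0.37 in heart between mdx and wild type (brightest probe set).

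**Figure D1:**
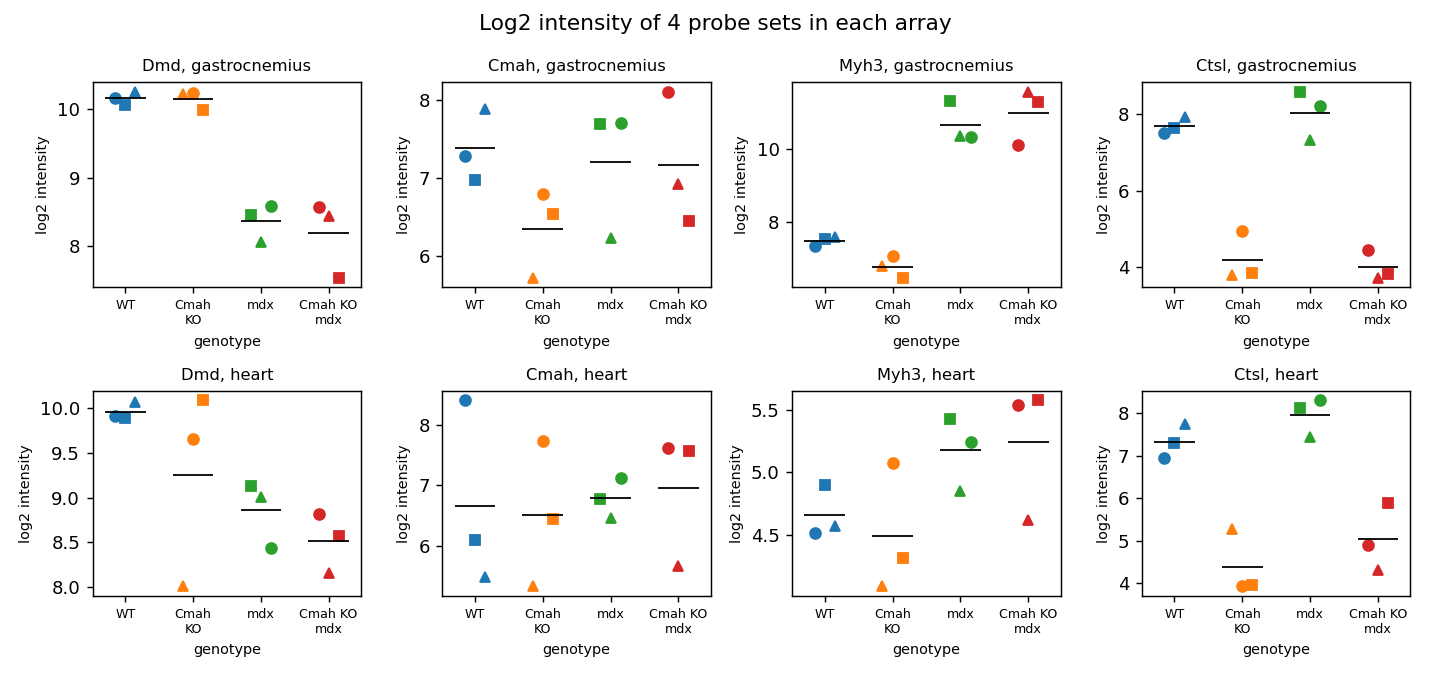
Log2 intensity of 1 probe set each of Dmd, Cmah, Myh3 and Ctsl in every array of gastrocnemius and heart, by genotype; each point is 1 animal, the marker shape gives its animal set (circle 1, square 2, triangle 3), the line is the mean of 3 animals, and each panel has its own scale. Ctsl lies lower in both Cmah-deficient groups in both tissues, and Myh3 lies higher in both dystrophin-deficient groups in gastrocnemius.

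With Cmah intact, developmental myosins were higher in mdx than in wild type gastrocnemius. Myh3, the embryonic myosin heavy chain, rose from 7.49 ± 0.14 in wild type to 10.67 ± 0.56 in mdx (SD, n = 3, limma adjusted p = 0.0363). Myh8, the perinatal myosin heavy chain, rose by 4.04 ± 0.53, and Pclo, which encodes a presynaptic scaffold protein, rose by 2.76 ± 0.29. Cdh4, a cadherin, fell by 3.05 ± 0.27. With Uqcr10, a subunit of respiratory complex III (up by 4.88 ± 0.55 at a probe set that is not its brightest), these made up all 5 probe sets past the threshold among 29518 tested in this comparison, 4 up and 1 down, with no overlap between the groups in any of them, a separation that chance gives 10% of the time. The wild type means of Pclo (3.42) and Uqcr10 (3.57) lay below the 40th percentile of all gastrocnemius values (4.66), so that the size of their rises is uncertain. Of the other Uqcr10 probe sets tested, 1 read 2.80 and 1 read -0.25 without passing, and Uqcr10 lies on chromosome 11 beside other genes with small p in mdx hearts. At an unadjusted p below 0.05 there were 1064 probe sets. Evenly spread p, with no change at all, would give 1476, so this count does not speak for further changes. The same holds for the other gastrocnemius comparisons and the interaction, except Cmah knockout mdx against Cmah knockout (2292). Values that did not pass included Myl4, the embryonic light chain (2.50 ± 0.41), Shisal1 (2.16 ± 0.34), Dusp26 (-2.81 ± 0.40), 0610040J01Rik (-2.03 ± 0.29) and Cntnap2 (-2.41 ± 0.45). The count was 0 when limma was given the arrays of these groups alone, 38 with the animal sets as a block, and 3, 1, 2 and 9 without WT replicate 1, WT replicate 2, mdx replicate 2 and mdx replicate 3.

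Gene lists of regeneration, inflammation and matrix were higher in mdx gastrocnemius by camera with the preset correlation, and none of these calls held with an estimated one. Of 38 lists, 13 passed the preset test in limma, 12 up and 1 down. The list of regenerating and embryonic muscle rose by a median of 1.03, with 20 of 21 members higher, 2 past the threshold over all genes (Myh3 and Myh8) and 8 when adjusted over the list alone. Macrophage genes rose by a median of 1.45, with all 29 members of that list higher, none past the threshold over all genes and 15 when adjusted over the list alone; Gpnmb read 3.13 ± 0.56 and Lgals3, which encodes galectin-3, read 2.88 ± 0.51. Interferon response genes rose by 0.96 (18 of 18 higher, 4 adjusted over the list alone), with Oasl2 at 1.84 ± 0.52 and Rsad2 at 1.43 ± 0.40. Cytokines and chemokines rose by 0.85 (3 adjusted over the list alone), with Il1rn at 2.76 ± 0.67. Il1rn in wild type (4.13), and Il6 in both groups (4.32 and 2.68), lay below the 40th percentile of all gastrocnemius values (4.66), so the size of the first is uncertain and none is given for Il6. Extracellular matrix genes rose by 0.73 (29 of 30 higher, 2 adjusted over the list alone), with Timp1, an inhibitor of matrix proteases, at 2.91 ± 0.73 and Mmp14 at 0.89 ± 0.24. Complement genes rose by 0.78, with C3ar1 at 2.23 ± 0.54 and Cd59a at -0.99 ± 0.29. Basement membrane genes rose by 0.35, with Nid2 at 0.66 ± 0.35 and Col15a1 at 0.49 ± 0.33. Fibroblast genes rose by 0.33, with Pdgfra at 0.58 ± 0.28 and Fap at 0.58 ± 0.43.

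For these 8 lists the preset test gave adjusted p between 1.58e-26 and 0.0219, and none held with an estimated correlation (adjusted p = 0.13 to 0.576). Their medians were above 0 in each of the 3 animal sets, from 0.89 to 1.31 for regenerating muscle and from 0.32 to 2.42 for macrophages, and all 8 passed with the sets as a block (adjusted p at most 0.00702). The sets were found from these same arrays, which favours both outcomes, so neither is independent support. Fry called regenerating muscle (adjusted p = 0.0465) and no other list in its directional form. The preset calls of basement membrane genes (0.21, 0.18 and 0.0566 without WT replicate 2, WT replicate 3 and mdx replicate 3) and fibroblast genes (0.36 and 0.21 without WT replicate 2 and mdx replicate 3) were lost when 1 of these arrays was left out. Cell cycle (0.69), immediate early (0.40), antigen presentation (0.35), cardiac stress (0.06) and B cell and immunoglobulin (-1.32) genes also passed the preset test, with adjusted p = 0.251 to 0.831 with an estimated correlation, and their medians differed in sign between the sets. Of the 13 preset calls 11 held with the sets as a block, and those lost were among these lists. The B cell value rested on WT replicate 1, whose removal gave 0.21.

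With Cmah also absent, the same myosins and further genes of regeneration and phagocytes rose with dystrophin loss. Cmah knockout mdx differed from Cmah knockout at 33 probe sets in gastrocnemius, 27 up and 6 down, again with no overlap between the groups. At an unadjusted p below 0.05 in limma it differed at 2292, where evenly spread p would give 1476. Myh3 rose from 6.78 ± 0.30 to 11.01 ± 0.77 (SD, n = 3, limma adjusted p = 0.00379) and Myh8 by 4.65 ± 0.53. Mymk, the myoblast fusion protein myomaker, rose by 4.05 ± 0.56. Clec7a (3.54 ± 0.55) and Lgals3 (3.27 ± 0.51), both macrophage genes, passed at their brightest probe set. Msr1, a macrophage scavenger receptor, rose by 3.11 ± 0.46 at another than its brightest. Mmp12, macrophage elastase, rose by 5.56 ± 0.85 and C1qtnf3 by 4.46 ± 0.56. Cdca5, needed for sister chromatid cohesion (4.03 ± 0.55), and the cell cycle transcription factor E2f2 (2.99 ± 0.46) rose as well, as did Gpr34 (3.44 ± 0.44). The Cmah knockout means of Mmp12 (3.42), Myh8 (4.51), C1qtnf3 (2.83), Mymk (3.70), Cdca5 (2.85), Gpr34 (3.91) and Msr1 (3.66) lay below the 40th percentile of all gastrocnemius values (4.66), so that the size and order of these rises are uncertain. Dusp26 fell by 3.27 ± 0.40, Cdh4 by 3.18 ± 0.27 and 0610040J01Rik fell by 2.73 ± 0.29, and Rims4 read -1.68 ± 0.29 without passing (adjusted p = 0.0543; its Cmah knockout mdx mean of 3.28 is low as well). The count was 2 in a fit of these groups alone and 459 with the animal sets as a block. Leaving out any 1 of the 6 arrays moved it, to 6, 2 and 2 without Cmah knockout replicates 1, 2 and 3 and to 70, 3 and 2 without Cmah knockout mdx replicates 1, 2 and 3.

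In this comparison 15 lists passed camera with the preset correlation, and none did with an estimated one (adjusted p = 0.104 to 0.606 for the 15). By the preset test the lists that rose included macrophages (median 1.98, 29 of 29 higher, 2 past the threshold over all genes and 23 adjusted over the list alone) and regenerating muscle (1.52, 20 of 21 higher, 4 over all genes and 13 adjusted over the list alone, among them Runx1 at 2.23 ± 0.33). Cell cycle genes rose by a median of 1.64, with 19 of 24 passing when adjusted over the list alone and none over all genes; Ccna2 read 3.25 ± 0.59 and Birc5 3.24 ± 0.65. Extracellular matrix genes rose by 0.92, with 13 of 30 adjusted over the list alone and 1 over all genes, Mmp14 (1.54 ± 0.24). Cytokines and chemokines rose by 1.06 (4 adjusted over the list alone, and over all genes Ccl8, a chemokine, at 1.96 ± 0.31), and interferon response genes by 0.95 (4 adjusted over the list alone), with Oas1a at 1.90 ± 0.47. Antigen presentation (0.71), neutrophil (0.80), basement membrane (0.49), complement (0.42) and fibroblast (0.32) genes rose too. Fatty acid oxidation genes fell by 0.28, all 22 lower, with Cd36, a fatty acid transporter, at -0.71 ± 0.30. Adipocyte genes fell by 0.79, all 11 lower, with Retn at -1.47 ± 0.57, and circadian clock genes by 0.38 (2 adjusted over the list alone), with Hlf at -1.78 ± 0.37.

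These 14 lists kept the sign of their median in each of the 3 animal sets and passed with the sets as a block (adjusted p at most 0.036). The way the sets were found favours both outcomes. The preset calls of neutrophil (0.74 and 0.62), complement (0.22 and 0.30), fibroblast (0.26 and 0.23) and antigen presentation genes (0.42 and 0.69) were lost without Cmah knockout replicate 1 and without Cmah knockout mdx replicate 3, the last also without Cmah knockout mdx replicate 2 (0.64). The other of the 15 was unfolded protein and heat shock (-0.10), whose sets differed in sign. Fry called 7 lists in one direction, namely regenerating muscle, macrophage, cell cycle, extracellular matrix, circadian clock, and cytokines and chemokines with adjusted p = 0.0092 to 0.0398, besides 1 list not called by camera.

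Dystrophin loss gave related changes with and without Cmah in gastrocnemius. Of the probe sets past the threshold, 4 were shared in the same direction, Myh3, Myh8 and Pclo up (3, where chance gives 0.00366) and Cdh4 down (1, where chance gives 2.03e-04), and none in opposite directions. Across 13232 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.649. Both comparisons cross the same strain labels and share no arrays. They do share the estimate of spread of each probe set, since 1 fit holds all 4 groups. A small spread favours a call in both, so the numbers given for chance are too low.

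**Figure D2:**
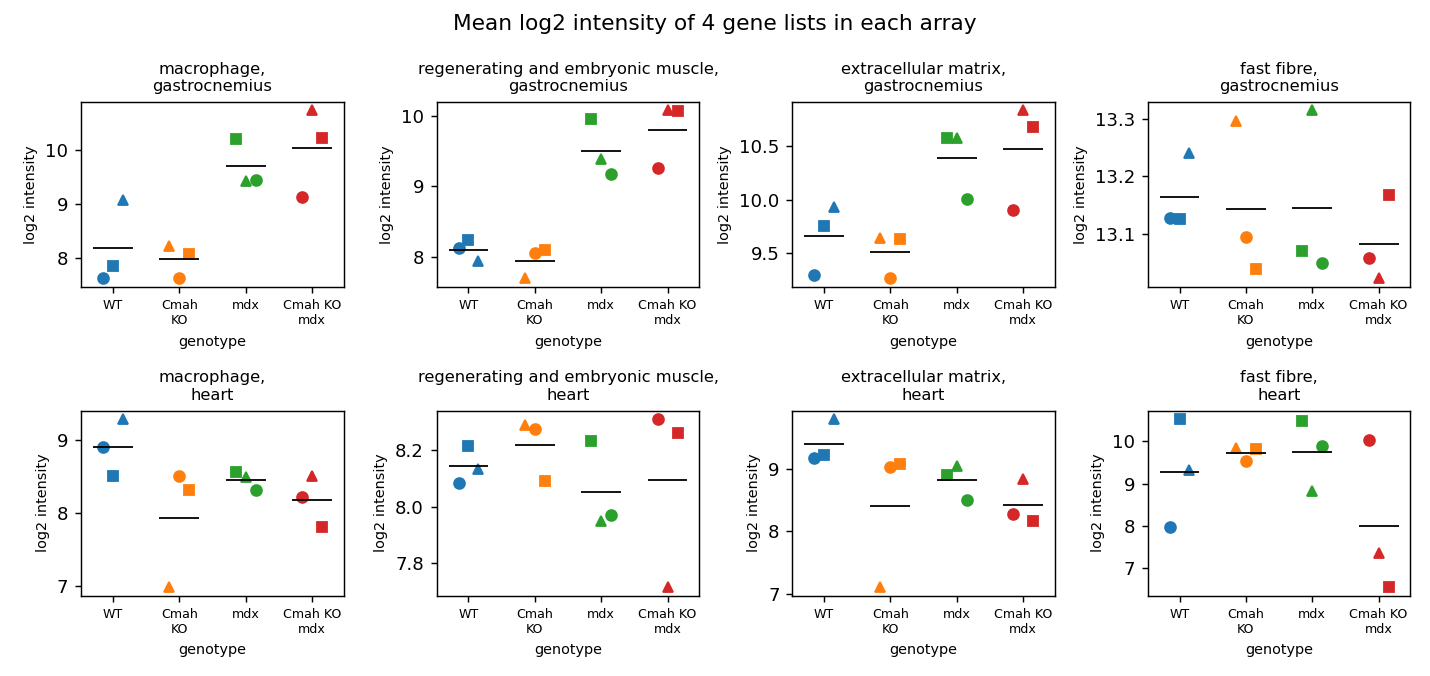
Mean log2 intensity of the macrophage, regenerating and embryonic muscle, extracellular matrix and fast fibre lists in every array of gastrocnemius and heart, by genotype; each point is 1 animal, the marker shape gives its animal set (circle 1, square 2, triangle 3), the line is the mean of 3 animals, and each panel has its own scale. In gastrocnemius the dystrophin-deficient groups lie higher in the first 3 lists, and in heart the fast fibre list ranges from 6.56 to 10.5.

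Between gastrocnemius groups that differ in Cmah, 1 probe set passed the threshold. Ctsl, which encodes the lysosomal protease cathepsin L, fell by 4.04 ± 0.40 in Cmah knockout mdx against mdx at 1 of its probe sets (limma adjusted p = 0.0130), the 1 probe set past the threshold in that comparison among 29518 (274 at an unadjusted p below 0.05). Ctsl lies on chromosome 13, as do Cmah, Prxl2c, Zfp874a and Arsk. Its Cmah knockout mdx mean of 4.00 lay below the 40th percentile of all gastrocnemius values (4.66), so that the size of the fall is uncertain. The probe set is not the gene's brightest, and the other Ctsl probe set tested read 0.42. In Cmah knockout against wild type the same probe set read -3.49 ± 0.40 (adjusted p = 0.0601), and 0 probe sets passed limma's threshold (332 at an unadjusted p below 0.05). Each of 6 alternatives gave 1 there, among them a quantile normalization, array weights and leaving out Cmah knockout replicate 1. The Ctsl call was lost without animal set 1 (-4.19, limma adjusted p = 0.103), in a fit of these groups alone (limma adjusted p = 0.0595) and without mdx replicate 1 (0.0642), mdx replicate 2 (0.119), Cmah knockout mdx replicate 2 (0.151) or Cmah knockout mdx replicate 3 (0.144), with log2 changes of Ctsl between -4.04 and -3.77, and the count was 0 without each of the last 3.

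Named genes that did not pass included Prxl2c, at -1.47 ± 0.31 with dystrophin and -2.01 ± 0.31 without, the zinc finger gene Zfp874a (-2.80 ± 0.56 and -2.88 ± 0.56) and the netrin receptor gene Unc5a (-1.22 ± 0.27 and -1.40 ± 0.27). The other Prxl2c probe set tested moved the opposite way, at 0.87 and 1.17, so a fall of the transcript is uncertain. The Cmah-deficient means of Zfp874a (3.81 and 3.95) and Unc5a (4.62 and 4.45) lay below the 40th percentile of all gastrocnemius values (4.66). The same held for 1 group each of Trim6, Hook2, 6230400D17Rik, Lrrc15 and Nusap1, so the sizes of these changes are uncertain. With dystrophin, Rsl1 read -2.23 ± 0.47, Trim6 -1.43 ± 0.33, the histone gene H3c11 1.88 ± 0.41, Rasd2 1.61 ± 0.49, Selp 1.25 ± 0.39, Nhlrc1 0.95 ± 0.29 and Hook2 0.79 ± 0.25. Without dystrophin, Slc15a2 read -2.59 ± 0.57, Mcur1 -1.11 ± 0.25, Rnf180 1.33 ± 0.39, 6230400D17Rik 1.00 ± 0.31, Lrrc15 1.27 ± 0.39, and Nanos1 0.86 ± 0.27. Like Prxl2c and Zfp874a, the genes Unc5a, Rsl1, H3c11, Nhlrc1, Mcur1 and Rnf180 lie on chromosome 13, which carries Cmah. They belong to the genes on that chromosome weighed under other observations. Between both readings of Cmah loss no probe set could be shared, since 0 passed in Cmah knockout against wild type. The log2 changes had an r of -0.05 across 13232 genes.

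With Cmah loss in dystrophin-positive gastrocnemius, 12 of the 38 lists passed the preset test and none held with an estimated correlation. Cell cycle genes fell by a median of 0.47 in Cmah knockout against wild type (22 of 24 lower, none past the threshold over all genes or adjusted over the list alone; Mki67, a proliferation marker, at -1.68 ± 0.63 and Nusap1 at -1.64 ± 0.75). Extracellular matrix genes fell by 0.21, with Col5a2 at -0.59 ± 0.35, and basement membrane genes by 0.16, with Nid1 at -0.64 ± 0.41 and Col4a1 at -0.40 ± 0.24. These 3 had the same sign in each animal set and passed with the sets as a block (adjusted p at most 0.00722), both favoured by the way the sets were found. They did not pass with an estimated correlation (adjusted p = 0.559 to 0.63). Without WT replicate 1 and without Cmah knockout replicate 1 the preset calls of extracellular matrix (-0.10 and -0.11) and basement membrane genes (-0.17 and -0.24) were lost. The other 9 lists that passed the preset test (adjusted p = 0.527 to 0.793 with an estimated correlation) differed in sign between the sets, among them neutrophil (-1.48, 4 of 7 lower when adjusted over the list alone, of which Mmp8 lay below 4.66 in both groups), T and NK cell (-0.56), macrophage (-0.17) and immediate early (0.46) genes. Of the 38 lists, 7 and 5 passed without WT replicate 1 and Cmah knockout replicate 1. The mean of the B cell list was 9.39 log2 intensity in WT replicate 1 and 7.35 in Cmah knockout replicate 3, against 4.93 to 6.00 in the other 10 gastrocnemius arrays, and without WT replicate 1 the macrophage, T and NK cell, B cell and interferon medians were 0.25, 0.43, 0.14 and 0.05. The T and NK cell list then passed in the opposite direction (adjusted p = 0.0419).

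In dystrophin-deficient gastrocnemius, Cmah loss came with lower fatty acid oxidation genes (a fall by a median of 0.14, 18 of 22 lower, Cd36 at -0.47 ± 0.30) and lower circadian clock genes (a fall by 0.22, 13 of 17 lower, Hlf at -0.92 ± 0.37 and Per2 at -0.94 ± 0.44). Both lists kept their sign in each animal set and passed with the block (adjusted p = 1.99e-04), which the way the sets were found favours. Neither passed with an estimated correlation (adjusted p = 0.219). Cell cycle (0.52), macrophage (0.31), adipocyte (-0.48) and immediate early (-0.12) genes also passed the preset test, with adjusted p = 0.722 with an estimated correlation, and differed in sign between the sets, with the cell cycle median at 0.03, -0.35 and 1.76 and the macrophage median at -0.32, -0.01 and 1.26. Of the 6 preset calls 4 held with the block, and those lost were among these lists. Without mdx replicate 3 no list passed, and without Cmah knockout mdx replicate 2 only 2 of the 38 did, neither of them fatty acid oxidation or circadian clock. The fatty acid oxidation median was 0.00 without Cmah knockout mdx replicate 1, with its call lost. The lists of sialic acid metabolism (0.31), sialyltransferases (0.05), siglecs (0.29) and regenerating muscle (0.22) did not pass.

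The interaction asked whether Cmah loss acts differently with and without dystrophin. Its readings of Cmah loss carry different strain labels, so that dystrophin status and strain cannot be told apart in it. In gastrocnemius 0 probe sets passed limma's threshold (311 at an unadjusted p below 0.05). Trim6 at 1.92 ± 0.46 and, on chromosome 13, Elovl7 at 2.63 ± 0.65 were among the values with the smallest p. Both had group means below the 40th percentile of all gastrocnemius values (4.66), so their sizes are uncertain. Mmp8, a neutrophil protease with a small p as well, lay below it in all 4 groups, so no value is given. Without mdx replicate 1 there was 1. Of the lists, 10 passed the preset test and none held with an estimated correlation (adjusted p = 0.13 to 0.822). Cell cycle genes rose by a median of 1.03 in this term (24 of 24 above 0, adjusted p = 0.208 with an estimated correlation), though the set medians were 0.53, 0.06 and 2.84, and neutrophil genes rose by 1.43 (7 of 7 above 0, adjusted p = 0.208 with an estimated correlation). In heart 0 probe sets passed (143 at an unadjusted p below 0.05).

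Heart arrays differed more in quality than those of gastrocnemius. For heart genes named below, group means under 4.78, the 40th percentile of all heart values, make the size of a change uncertain. This holds for 1 group each of Tnmd, Cd3d, Ankrd63, Cthrc1, Ereg and Sprr1a across dystrophin loss. Across Cmah loss it holds for Blk, Cd22, Ighg3, Igll1, Slc27a2, Ms4a1, Fcrla, Elovl7, Naip5, Zfp874a and, with dystrophin, the Ctsl probe set. In heart the 3' minus 5' log2 difference of Gapdh was 4.29 in Cmah knockout replicate 3 and 4.43 in Cmah knockout mdx replicate 2, and their median correlations with the other hearts were 0.543 and 0.857. The difference of Gapdh was 0.98 to 1.60 in the 4 hearts of animal set 1 and 0.44 to 0.54 in the other 6. Set 1 also had the highest values in gastrocnemius, at 0.76 to 1.02 against 0.36 to 0.71 in the other 8 arrays, so that leaving out set 1 also leaves out arrays that differ in this measure. The median log2 change over all probe sets was -0.37 in Cmah knockout against wild type, -0.14 in Cmah knockout mdx against mdx and 0.20 in Cmah knockout mdx against Cmah knockout, so that changes in these comparisons stand against those shifts. In heart 0 of 29421 probe sets passed limma's threshold in each of the 4 comparisons of groups. At an unadjusted p below 0.05 there were 103 for mdx against wild type, 568 for Cmah knockout mdx against Cmah knockout, 250 for Cmah knockout against wild type and 464 for Cmah knockout mdx against mdx. Evenly spread p would give 1471, so these counts, and that of the heart interaction, do not speak for changes short of the threshold. With array weights, limma called 133, 0, 1 and 19 in the same order, and without the 2 deviating arrays it called 0 in each.

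Matrix and tendon genes were lower in mdx than in wild type hearts by the preset test, of which only the tendon call held with an estimated correlation. The tendon list fell by a median of 0.61 (8 of 9 lower), with Tnmd, tenomodulin, at -1.44 ± 0.52 and Thbs4 at -0.98 ± 0.48, and it was the 1 list call of any comparison that held with an estimated correlation (adjusted p = 0.0156, or adjusted p = 0.0869 with an estimated correlation and the animal sets as a block). It did not hold with an estimated correlation without the 2 deviating arrays (adjusted p = 0.321), and fry did not call it (adjusted p = 0.626 in its directional form). Extracellular matrix genes fell by 0.46 (27 of 30 lower, none past the threshold over all genes and 1 adjusted over the list alone), with Postn, periostin, at -2.01 ± 0.49 and Tnc, tenascin C, at -1.83 ± 0.54. Cardiac stress genes fell by 0.53 and interferon response genes by 0.26. Antigen presentation genes fell by 0.33 (H2-Aa at -0.52 ± 0.40), T and NK cell genes by 0.48 (Cd3d at -0.97 ± 0.55) and unfolded protein and heat shock genes by 0.18 (Hspa1b at -1.89 ± 0.74), while circadian clock genes rose by 0.60 (Dbp at 1.25 ± 0.58, but Arntl at -1.38 ± 0.69) and fatty acid oxidation genes by 0.11 (Ucp3 at 1.505 ± 0.464). Apart from tendon, these 8 lists were not called with an estimated correlation (adjusted p = 0.181 to 0.75). All 9 had the same sign in each animal set, and fatty acid oxidation was lost with the sets as a block (adjusted p = 0.0568). It was also lost without WT replicate 2, WT replicate 3 or mdx replicate 3 (medians of 0.00, 0.22 and 0.0395). Circadian clock was lost without WT replicate 2 (0.30). In all, 14 of the 38 lists passed, and the other 5, adipocyte (0.60), erythroid (0.44), macrophage (-0.35), cell cycle (-0.41) and cytokines and chemokines (-0.21), differed in sign between the sets (adjusted p = 0.181 to 0.449 with an estimated correlation). Of the 14 preset calls, 10 held without the 2 deviating arrays. The 4 lost were fatty acid oxidation (adjusted p = 0.0536), adipocyte (0.0593), erythroid (0.0661) and cytokines and chemokines (0.118) genes, with the same medians, since neither array is in this comparison. Single genes that did not pass included Ankrd63 (1.93 ± 0.50), Ky (1.20 ± 0.39), Acot1 (1.34 ± 0.45), Art5 (1.24 ± 0.46), Sprr1a (-2.05 ± 0.44), Cthrc1 (-2.17 ± 0.62) and Ereg (-2.10 ± 0.61).

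In hearts without Cmah, the fast fibre list passed the preset test with dystrophin loss, with a direction that depended on the fit. Fast fibre genes fell by a median of 2.06 in Cmah knockout mdx against Cmah knockout (12 of 14 lower, adjusted p = 0.524 with an estimated correlation), with Tnnt3 at -3.34 ± 1.18 and Atp2a1 at -2.87 ± 1.09. The set medians were 0.54, -3.86 and -3.22. The median of fast fibre genes was -3.32 without Cmah knockout mdx replicate 1, -1.11 without Cmah knockout mdx replicate 2, -0.78 without the 2 deviating arrays and 0.0412 without them and with the animal sets as a block, which turns its direction. Cardiac stress (-0.73), tendon (-0.58) and T and NK cell (-0.37) genes also passed and differed in sign between the sets (adjusted p = 0.35 to 0.58 with an estimated correlation). The T and NK cell call was lost without the 2 deviating arrays (-0.19). Values that did not pass included S100a8 (2.33 ± 0.63), Cpxm2 (-2.93 ± 0.63), Acta1, skeletal alpha-actin (-2.45 ± 0.69), and Sprr1a (-1.97 ± 0.44). Between both readings of dystrophin loss no probe set could be shared in heart, since 0 passed in either. The log2 changes had an r of 1.14e-04 across 13128 genes (0.0717 without the 2 deviating arrays).

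B cell genes were higher with Cmah loss in heart by the preset test, and the estimated correlation ended both calls (adjusted p = 0.426 and adjusted p = 0.588 with an estimated correlation). The B cell and immunoglobulin list rose by a median of 1.68 in Cmah knockout against wild type (9 of 9 higher), with the immunoglobulin heavy chain gene Ighm at 3.39 ± 1.13 and the kinase gene Blk at 1.68 ± 0.60. In Cmah knockout mdx against mdx it rose by 1.26 (9 of 9 higher), with Ms4a1, which encodes CD20, at 2.39 ± 0.99 and Fcrla at 1.39 ± 0.57. No member passed over all genes or adjusted over the list alone. The set medians were 1.02, 2.23 and 1.52 with dystrophin and 0.14, 1.77 and 2.09 without, and the medians were 1.57 and 1.19 without the 2 deviating arrays. Without Cmah knockout mdx replicate 3 the preset call without dystrophin was lost (0.37, adjusted p = 0.269). In gastrocnemius of the same animals the list read -0.86 and -0.24, the first of which became 0.14 without WT replicate 1.

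Other lists in heart moved with the deviating arrays. In Cmah knockout against wild type, macrophage genes fell by 1.08 (Fcgr3 at -1.31 ± 0.51), extracellular matrix genes by 0.94 (Tnc at -1.95 ± 0.54) and interferon response genes by 0.80 (Rsad2 at -1.48 ± 0.74), and siglecs rose by 0.45 (Cd22 at 1.53 ± 0.55), each with the same sign in every animal set and passing with the block (adjusted p at most 0.0192). None held with an estimated correlation (adjusted p = 0.426 to 0.946). Without the 2 deviating arrays the first 3 read -0.45, -0.28 and -0.32 and still passed, and siglecs read 0.00 and did not. Without Cmah knockout replicate 2 all 4 calls were lost (-1.32, -1.05, -1.06 and 0.59). Interferon response was also lost without WT replicate 2 (-0.66) and Cmah knockout replicate 1 (-1.17). Siglecs were lost without WT replicate 2 (0.26) and Cmah knockout replicate 3 (0.00). Fast fibre genes (0.49) also passed and differed in sign between the sets (adjusted p = 0.946 with an estimated correlation), and read 0.0331 without passing once the 2 arrays were left out. In Cmah knockout mdx against mdx, endothelial genes fell by 0.66 (13 of 13 lower, Kdr at -1.08 ± 0.58; adjusted p = 0.926 with an estimated correlation), which became -0.29 without passing once the 2 arrays were left out. The call was lost without mdx replicate 1 (-0.54). It was also lost without Cmah knockout mdx replicates 1 and 2 (-0.62 and -0.29) and without replicate 3. Fast fibre genes fell by 2.15 in that comparison (12 of 14 lower, Atp2a1 at -2.64 ± 1.09; adjusted p = 0.588 with an estimated correlation), with set medians of 0.07, -4.85 and -1.70. This call was lost without Cmah knockout mdx replicate 3 (-1.65). The fall was larger without Cmah knockout mdx replicate 1, and the median was -1.33 without the 2 deviating arrays.

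Among single genes in heart, the same Ctsl probe set read -2.94 ± 0.54 and -2.92 ± 0.54, Zfp874a read -2.93 ± 0.62 and -2.95 ± 0.62 and Prxl2c -2.16 ± 0.56 and -2.35 ± 0.56 with and without dystrophin, and none passed. The other probe sets tested read -0.70 and -0.65 for Ctsl and -0.30 and 0.53 for Prxl2c. Igll1 (3.23 ± 0.79), Ighg3 (2.79 ± 0.77) and Slc27a2 (2.26 ± 0.65) had small p in Cmah knockout against wild type without passing, as had Elovl7 (2.41 ± 0.51), Arsk (-2.40 ± 0.56) and Naip5 (-2.02 ± 0.49) in Cmah knockout mdx against mdx. Elovl7, Arsk and Naip5 lie on chromosome 13, and the other Arsk probe set tested read 1.12. The log2 changes of both comparisons had an r of 0.368 across 13128 genes, and no probe set could be shared, since 0 passed in either. Each comparison holds 1 of the 2 deviating arrays in its Cmah-deficient group, and without both the r was 0.167.

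The tissues of the same animals were compared by a test of the difference. For single genes 0 of 31070 probe sets passed limma's threshold in each comparison. At an unadjusted p below 0.05 there were 727 for mdx against wild type, 873 for Cmah knockout against wild type and 376 for Cmah knockout mdx against mdx. Each is fewer than the share of 0.05 that evenly spread p would give. Gpnmb, a macrophage gene, had one of the smallest p for mdx against wild type, at 3.13 in gastrocnemius and -1.85 in heart. Without the 2 deviating hearts 8 probe sets passed for mdx against wild type, and 3 and 1 passed without the gastrocnemius array of WT replicate 1 and the heart array of WT replicate 2. By lists, the response of heart to dystrophin loss lay below that of gastrocnemius by 1.89 for macrophage genes, by 1.36 for regenerating muscle and by 1.22 for extracellular matrix, and 16 lists passed this test with the preset correlation, which was the only form run.

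**Figure D3:**
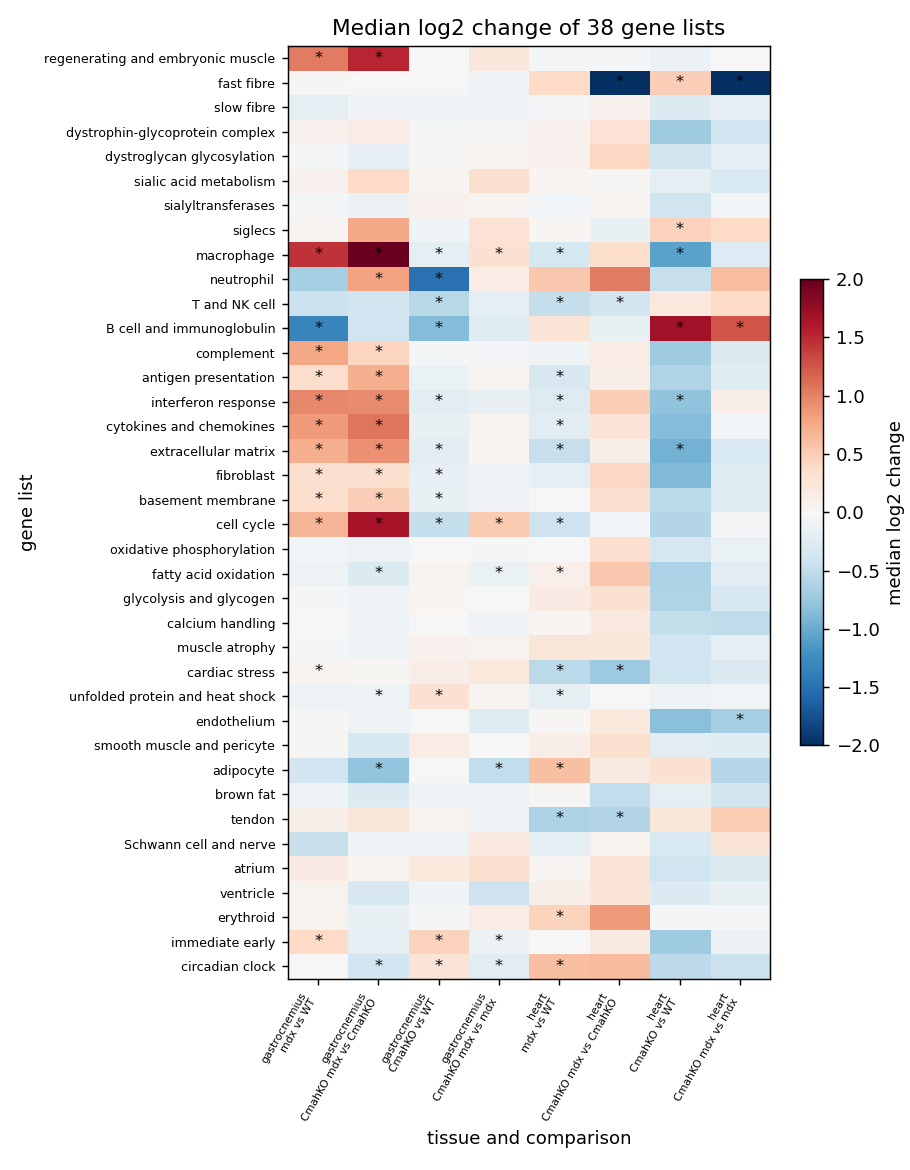
Median log2 change of each of the 38 gene lists (vertical axis) in 4 comparisons of gastrocnemius and of heart (horizontal axis); colour gives the median log2 change, limited to between -2 and 2, and an asterisk marks an adjusted p below 0.05 by camera with the preset correlation. Macrophage, regenerating muscle and matrix lists rose in both comparisons across dystrophin loss in gastrocnemius, and B cell genes rose in both comparisons across Cmah loss in heart, and none of these calls held with an estimated correlation.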

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

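The tests of the fast fibre list in heart and the repeats of the tissue differences without an array were chosen only after the result was seen, whereas the tests of a difference between tissues or between both readings of Cmah loss were planned. The values here are median log2 differences of gene lists whose test of that difference passed with the preset correlation. Of the 86 preset list calls within a tissue, 85 were lost with an estimated correlation, a form that was not run for differences between tissues.

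By the preset test, the only form run, the response to dystrophin loss with Cmah intact differed between the tissues, given as heart minus gastrocnemius. It was lower in heart for macrophage (-1.89), regenerating muscle (-1.36), interferon response (-1.32), extracellular matrix (-1.22), cytokine and chemokine (-1.14), cell cycle (-1.10), complement (-0.86), tendon (-0.74), antigen presentation (-0.66), cardiac stress (-0.58), immediate early (-0.49) and fibroblast (-0.45) genes. It was higher in heart for B cell (1.54), adipocyte (0.71), circadian clock (0.49) and fatty acid oxidation (0.23) genes. When each of the 12 arrays compared was left out in turn, 10 of these 16 calls were kept in every fit. Among these 10, antigen presentation genes ranged from -1.40 to -0.242 (adjusted p up to 0.0371), complement genes from -1.03 to -0.432, cardiac stress genes from -1.11 to -0.468, cell cycle genes from -1.27 to -0.710 and tendon genes from -0.933 to -0.483. B cell genes read 0.0580 without the gastrocnemius array of WT replicate 1 (adjusted p = 0.634), and the calls of fibroblast, fatty acid oxidation, adipocyte, immediate early and circadian clock genes were lost in 1 to 3 fits each. Immediate early genes ranged from -0.907 to -0.233 and fatty acid oxidation genes from 0.148 to 0.280. Circadian clock genes read 0.0721 without the heart array of WT replicate 2, and adipocyte genes 0.319 and 1.51 without the gastrocnemius arrays of WT replicates 1 and 3.

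By the same test the response to Cmah loss with dystrophin present differed between the tissues for B cell (2.66), neutrophil (1.88), T and NK cell (0.81), tendon (0.55), siglec (0.47), fast fibre (0.45), regenerating muscle (0.30), cell cycle (0.18), extracellular matrix (-0.65) and immediate early (-1.19) genes. These stand against median changes over all probe sets of -0.37 in heart and 0.04 in gastrocnemius. Without dystrophin it differed for B cell (1.13), tendon (0.47), interferon response (0.22), macrophage (-0.57), cell cycle (-0.70) and fast fibre (-2.14) genes. With dystrophin only the B cell call was kept whichever array was left out (0.866 to 3.97, the lowest without the gastrocnemius array of WT replicate 1), and without dystrophin none was. Without the gastrocnemius array of WT replicate 1 the T and NK cell difference turned to -0.372. The differences of fast fibre and cell cycle genes with dystrophin (down to -0.223 and -0.288) and of interferon response genes without it (down to -0.0382) also turned when 1 array was left out. Siglecs read 0.0156 without the gastrocnemius array of WT replicate 1. Without the heart array of Cmah knockout replicate 3, extracellular matrix genes read -0.0338, regenerating muscle genes 0.0744 and immediate early genes -0.436. The range was 1.13 to 2.18 for neutrophil and 0.259 to 0.566 for tendon genes. Without dystrophin it was 0.455 to 1.75 for B cell, -1.13 to -0.234 for macrophage, -1.05 to -0.210 for cell cycle and -3.53 to -1.19 for fast fibre genes.

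By the preset test the response to Cmah loss also differed between groups without and with dystrophin, which differ in strain label too. Values are the response without minus the response with dystrophin. In gastrocnemius the lists were neutrophil (1.43), cell cycle (1.03), macrophage (0.41), regenerating muscle (0.41), extracellular matrix (0.27), unfolded protein and heat shock (-0.0834), fatty acid oxidation (-0.17), circadian clock (-0.54), adipocyte (-0.55) and immediate early (-0.74), none of which held with an estimated correlation (adjusted p = 0.13 to 0.822). The adipocyte call was lost in 7 of the 12 fits that left out 1 array, and its test turned without WT replicate 3 (-0.0161, adjusted p = 0.987). Calls of regenerating muscle, macrophage, extracellular matrix, fatty acid oxidation and unfolded protein genes were lost in 3 to 6 of these fits each. In heart they were interferon response (0.91), macrophage (0.67) and fast fibre (-2.53), each with adjusted p = 0.988 with an estimated correlation. Without Cmah knockout replicate 2 the interferon response and macrophage calls were lost, and the macrophage call was also lost without WT replicate 3 and without Cmah knockout mdx replicate 3.

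Fast fibre genes, which skeletal muscle expresses strongly, were lower in Cmah knockout mdx than in mdx hearts by the preset test (median -2.15; adjusted p = 0.588 with an estimated correlation). The call was also lost without Cmah knockout mdx replicate 3 (-1.65). Their mean ranged from 6.56 to 10.5 log2 intensity between hearts, against 13.1 in gastrocnemius. Among wild type hearts alone it ranged from 7.98 to 10.5, so part of this spread does not follow genotype. It was 7.37 in Cmah knockout mdx replicate 3, whose Gapdh difference was 0.48. Skeletal muscle taken along with some hearts is a candidate explanation: 8 other genes bright in gastrocnemius and lower in heart had a median change of -0.77, against -0.15 for the ventricle list. Fast fibre genes correlated with each other at a median of 0.734 over the 10 hearts without the 2 deviating arrays. The mean of those 8 genes lay between 8.08 and 10.2 in every heart. Among wild type hearts alone Pvalb ranged from 9.36 to 12.4 and Mylpf from 8.73 to 12.2. The 8 genes include Acta1, which is also in the cardiac stress list, so skeletal muscle taken along cannot be told apart from a change within the heart. Lower RNA quality of 1 heart is another candidate explanation, and without the 2 deviating arrays the median was -1.33 (adjusted p = 0.0116), or -0.77 with the animal sets as a block as well (adjusted p = 0.373), which leaves it open. A change of fast fibre genes by Cmah loss itself remains open and was not tested apart from these.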

How the results depend on the processing

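The animal sets, array weights, the 2 deviating hearts and list scalings were chosen as alternatives after the data were seen; the cause of each change was not tested except where stated. Probe sets past the threshold in gastrocnemius, for mdx against wild type (5), numbered 8 after quantile normalization, 8 after median centring, 38 with the animal set block, 2 without set 1, 9 with array weights, 13 with both tissues and 0 with only the groups compared. For Cmah knockout against wild type (0) there was 1 under each of the stricter filter, quantile normalization, the replicate block, array weights and both tissues. For Cmah knockout mdx against mdx (1) there were 2 after quantile normalization, 3 after median centring, 3 with the replicate block, 0 with 1 probe set per gene (the Ctsl probe set is then not tested), 2 with the set block, 2 without set 1 (the Ctsl probe set not among them), 5 with array weights and 4 with both tissues. For Cmah knockout mdx against Cmah knockout (33) there were 63 with 1 probe set per gene, 459 with the set block, 7 without set 1, 539 with array weights, 71 with both tissues and 2 with only the groups compared. The overlap of 4 became 31 with the set block. In heart, array weights gave 133 (mdx against wild type), 1 (Cmah knockout against wild type) and 19 (Cmah knockout mdx against mdx) in place of 0. The tissue difference for mdx against wild type became 8 without the 2 deviating hearts. Leaving out 1 array gave 1 to 9, 0 to 1, 0 to 1, 2 to 70 and 0 to 1 (interaction) in gastrocnemius, 0 to 0 in each heart comparison, and 0 to 3, 0 to 0 and 0 to 0 for the tissue differences. Lists past the threshold in gastrocnemius numbered 13, 12, 6, 15 and 10 in the same order, and 0 in each with an estimated correlation. Directional fry gave 1, 0, 0, 7 and 0, and mixed fry 2, 0, 0, 12 and 0. Without set 1 the 6 became 10. In heart they numbered 14, 6, 3, 4 and 3, and 1, 0, 0, 0 and 0 with an estimated correlation, and 0 in each by both forms of fry. Without the filter the 6, 3 and 3 (interaction) became 11, 11 and 5. With the mean of a gene's probe sets the 3 (Cmah knockout mdx against mdx) became 5 and the 4 became 7, and without set 1 that 3 became 6. Without the 2 deviating hearts, with and without the set block, the 4 became 9 and the interaction 7. Leaving out 1 array gave 9 to 13, 5 to 14, 0 to 11, 12 to 18 and 6 to 11 lists in gastrocnemius and 12 to 19, 1 to 10, 0 to 8, 4 to 8 and 1 to 7 in heart. Over the leave-one-out fits, list medians that turned together with the direction of their test ranged from -1.92 to 0.21 for B cell genes in mdx against wild type, and in Cmah knockout against wild type from -0.47 to 0.25 (macrophage), -1.21 to 0.43 (T and NK cell), -1.62 to 0.14 (B cell) and -0.538 to 0.0473 (interferon response), each turning without WT replicate 1. In Cmah knockout mdx against mdx they ranged from -0.00336 to 0.86 for macrophage genes, turning without Cmah knockout mdx replicate 2, and from -0.456 to 0.0502 for immediate early genes, turning without mdx replicate 3. For the adipocyte interaction they ranged from -1.21 to -0.0161, with the direction of the test turning without WT replicate 3. Medians of called lists also crossed 0 without a turn of the test: in heart fast fibre genes (Cmah knockout against wild type, -0.251 to 0.940, negative without WT replicate 2; -0.124 without set 1), and by at most 0.07 past 0 cytokine, fatty acid oxidation and unfolded protein genes (mdx against wild type), and in gastrocnemius cardiac stress (mdx against wild type), fatty acid oxidation (Cmah knockout mdx against mdx, without Cmah knockout mdx replicate 1) and unfolded protein genes (Cmah knockout mdx against Cmah knockout, and interaction). Fast fibre genes in heart read -0.0201 (Cmah knockout against wild type) and 0.0412 (Cmah knockout mdx against Cmah knockout) without the 2 deviating hearts and with the set block. Of 86 list calls none turned under either scaling, with 8 lost after quantile normalization and 1 after median centring. Dmd in mdx against wild type passed with the set block in gastrocnemius (adjusted p = 0.0387) and with array weights in heart (0.0386). The replicate numbers do not pair the animals, since arrays of the same number correlated from -0.577 to 0.615 in gastrocnemius and from -0.418 to 0.645 in heart. At this number of arrays and this spread, simulated changes of 1 on the log2 scale were recovered in 1.47% of cases. That share also depends on how many probe sets change, and the part due to the number of arrays was not tested.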

Other observations

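The tests of neighbouring genes on chromosomes 13 and 11 and the repeats of the interaction draws were chosen only after the result was seen, while the counts over other splits of the samples, the window around Cmah and the reading of Nnt were planned.

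Genes with the smallest p for Cmah loss lay close together in gene order on chromosome 13, which carries Cmah. Of the 50 genes with the smallest p, 13 and 14 lay on chromosome 13 in gastrocnemius with and without dystrophin (1.83 by its share of tested genes) and 8 and 11 in heart (1.86 by its share). Prxl2c, Ctsl, Zfp874a and Arsk were among the 50 in all 4 comparisons, and the other comparisons, across dystrophin loss, held 2 and 0 in gastrocnemius and 1 and 5 in heart. One-sided Fisher exact tests gave Benjamini-Hochberg adjusted p of 7.4e-08, 1.4e-08, 9.3e-04 and 4.4e-06 in the same order as the counts. Windows of 100 neighbouring tested genes held up to 7 and 9 of the 50 in gastrocnemius, with a permutation p of 0.001 for each, the smallest that 1000 permutations can give, and up to 4 in heart with dystrophin (permutation p = 0.206; with the animal sets as a block the densest window there lay on chromosome 2, with 3 genes and permutation p = 0.884). In heart without dystrophin the densest window lay on chromosome 11, and on chromosome 13 with the animal sets as a block (6 genes, permutation p = 0.001). The Fisher tests and these permutations, with those for chromosome 11 below, treat genes as independent. Neighbours that are read alike or move together are not separate hits, so p can be too small.

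DNA of the donor strain carried along with the Cmah deletion is a candidate explanation for these 13, 14, 8 and 11 genes, of which 3, 1, 3 and 1 lie in the planned window around Cmah (0.513 in gastrocnemius and 0.532 in heart by its share). These are H3c11, Hfe and Mcur1, then Mcur1, then H3c11, Hfe and Pgbd1, and then Foxq1, and none of the genes in the gastrocnemius windows above is among them. Those are parted from Cmah by 205 to 301 of the 482 tested genes of the chromosome, which a segment around Cmah alone would have to span. The planned test within 20 Mb of Cmah had too few called genes to run, at 0 and 1 in gastrocnemius and 0 and 0 in heart, none of them in that window. Sequence differences under single probe sets, with no change of the transcript, may also give this pattern. For 11 genes with several probe sets the other probe sets moved by a median of 0.0934 of the leading one, against 0.352 for 88 top genes on other chromosomes. A one-sided permutation test of the rank sum of these ratios gave p = 0.0790. It compares unlike and partly repeated units, so it cannot decide the question, which stays open. An effect of Cmah loss on these genes was not tested apart from these.

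A second run of neighbours lay on chromosome 11 in mdx hearts. Pik3ip1, Dusp18, Sf3a1, Uqcr10, Rasl10a and Ube2d-ps, 6 of the 50 genes with the smallest p in mdx against wild type, lay within 1 window (permutation p = 0.002; with the animal sets as a block 4 genes, permutation p = 0.201). The same stretch, with Nipsnap1 in place of Rasl10a, was the densest window in Cmah knockout mdx against mdx hearts (6 genes, permutation p = 0.002), a comparison that shares the mdx arrays. A DNA segment that differs between the mdx group and the other groups is a candidate explanation, and 4 of the 6 genes moved the same way at an unadjusted p below 0.05 in gastrocnemius of the same animals, where Uqcr10 also passed at another probe set. Dystrophin loss acting alike with and without Cmah would give similar changes in both comparisons. In heart the median change of the 6 genes was 1.96 in mdx against wild type and -0.30 in Cmah knockout mdx against Cmah knockout (quartiles -0.54 and 0.04). Choosing genes by p enlarges the 1.96, neighbours are not replicates, and the second comparison holds both deviating arrays. In gastrocnemius Dusp18, low in wild type (4.48), read 2.82 and -0.54, Sf3a1 1.95 and 0.14, Uqcr10 2.80 and -0.25 and Ube2d-ps 1.52 and -0.56. These values argue against it for those 4 genes.

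Strain was read at Nnt, part of which is deleted in C57BL/6J. Its brightest probe set differed across dystrophin loss by -0.15 ± 0.34 and -0.20 ± 0.34 in gastrocnemius and by 0.10 ± 0.37 and -0.0370 ± 0.37 in heart, with and without Cmah. These small values decide nothing, because it is not known whether its probes lie in the deleted part, so strain and dystrophin loss cannot be told apart.

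Other splits of the same 6 arrays number 10 with the real one, too few for a share under 0.05. In gastrocnemius 1 of the 10 gave as many probe sets as the real 5 for mdx against wild type, 1 as many as the real 1 for Cmah knockout mdx against mdx and 1 as many as the real 33 for Cmah knockout mdx against Cmah knockout, with 0 as the highest of the others each time. For Cmah knockout against wild type in gastrocnemius, and for mdx against wild type, Cmah knockout against wild type and Cmah knockout mdx against Cmah knockout in heart, limma gave a real count of 0, all 10 were as large, and the highest of the others was 0 (332, 103, 250 and 568 at an unadjusted p below 0.05). For Cmah knockout mdx against mdx in heart all 10 were as large as the real 0 and the highest of the others was 2 (464 at an unadjusted p below 0.05). For the tissue differences all 10 splits of the animals were as large as the real 0 in limma, with highest others of 0, 1 and 4 (727, 873 and 376 at an unadjusted p below 0.05). For the interaction all 100 draws were as large as the real 0 in each tissue, as any draw is against 0, so that they say nothing about chance (311 and 143 at an unadjusted p below 0.05 in limma). Of the other 99 draws, 3 gave any call in gastrocnemius and 2 in heart. The highest gave 65 in gastrocnemius and 4098 in heart. A structure of the samples and genes that move together may both give such draws, and they were not told apart. A split can be drawn more than once, so draws with equal counts may be the same split. With the same draws the highest was 83 in gastrocnemius and 16888 in heart with the animal sets as a block, and 14000 in heart without the 2 deviating arrays, where 9 of 99 draws gave calls, so neither of these removed high draws, though the 2 gastrocnemius draws with 65 gave 0 with the block.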
